A study of Mus musculus with 14 samples.

How the data were processed

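Total RNA of each sample was labelled with Cy5 and compared on a 2-colour Agilent array with a universal mouse reference labelled with Cy3, per the labels. Fibroblast RNA and skin RNA were extracted with different kits, per the labels' protocols, so the systems differ in more than their cells. All 14 arrays had the same dye orientation, and dyes were not swapped. The deposited values are log ratios, taken here as log2 of the sample over the reference. The base is not stated; values reached from -9.55 to 10.97, a range that log10 would put outside what a scanner can read. The direction follows the dyes in the labels, and keratins lay far above 0 in skin and not in fibroblasts, with Krt10 at a mean of 5.24 in Tsk2 skin and 0.095 in Tsk2-transfected fibroblasts. Column medians lay between 0 and 0.043, so each array appears centred, and genes were not centred across arrays. Feature extraction, background correction, normalization within arrays and filters are not given in the sources used here. Scanner files, intensities, slides and scan dates were not used here, so signal over background and batches could not be tested.

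Between 312 and 12391 probes per array were listed at exactly 0, with 12391 (30.1%) in WT skin replicate 2. Values repeated 50 times or more on an array made up 33.8% to 46.7% of its probes. In olfactory and vomeronasal receptor probes 86.9% of values were of this kind, against 7.37% in ribosomal protein and oxidative phosphorylation probes, so repeated values were read as a mark of dim probes. Both kinds were kept in the fits and left out as alternatives chosen after seeing the data, as was the test of lists for the difference between systems. Probes at repeated values were left out only if every group compared held such a value, so probes dim in only some groups stayed in. Such values narrow or widen the spread of dim genes.

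Of the 41174 probes, 32664 had 1 gene symbol in the platform annotation, 45 had several and 8465 were not listed in it and are unnamed here. Gene IDs of 19411 of the 19533 genes were found in a RefSeq table of assembly GRCm38.p6, and 0 symbols changed. A gene's value was the mean over its probes, with 11023 genes on 1 probe and 8510 on more. Among genes past the threshold, probes of a gene disagreed in sign for 4 in skin and 0 in fibroblasts. The build behind the probes is not named, so no coordinates are given. Columns that matched no sample numbered 0.

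Samples were grouped by the labels. The design text counts fewer mice per genotype than the labels hold, and all 4 per genotype were used. Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with defaults, two-sided, Benjamini-Hochberg threshold 0.05) on its own arrays, and the difference of the effects as a contrast on all 14. Genes needed values on 2 arrays of each fibroblast group and 3 of each skin group. Gene lists of at least 5 measured members, 36 in number, were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Designs, lists, named genes and alternatives were fixed before the data were examined, except where stated. The 36 lists cover matrix, signalling, stress, metabolism and markers of cell types that skin can hold.

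Genes were named by rule. Past the threshold and without overlap between groups, the 12 largest rises and 12 largest falls were taken, leaving out clone and locus names. Where a direction had few calls, the 8 genes of lowest p with a difference of at least 0.58 were added and are described as not past it. The rule allowed up to 4 members of each called or matrix list, of which the 3 of lowest p in fibroblasts and the 2 in skin were taken to keep their number down, and 11 matrix and TGF-beta genes were to be named whatever their values, of which 9 were measured and the others are not analysed here. List members without a value are not analysed here either. Msx2, Des, Tpm2, the hair-cycle genes Krt25 and Mki67, and Igf2 and H19 were chosen after their values were seen. The list of genes set beside Igf2 and H19 was fixed after these had been noticed but before the test over it was seen. Its members given with values were picked after.

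The fits were tested on data simulated from the arrays' means and spreads with 100 genes changed by 1 and 100 by 2 on the log2 scale. For the fibroblast comparison 39% and 66% of them were recovered over 19533 genes, with 10 false calls. In skin 29% and 78% were recovered over 19525 genes, with 3 false calls, and for the difference between systems 17% and 66%, with 7 false calls. Without changed genes the simulated fits gave 0 calls in each comparison. Camera called a list shifted by 0.5 in both systems and 0 lists without a shift, in simulated data without correlation between genes. Alternatives covered centring, quantile normalization, missing values, probe choice, array weights, 1 fit for all arrays, a replicate block for the transfection numbers, the mean of 2 like-numbered transfections and each array left out.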

Results

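Gene expression was measured on 14 whole-genome Agilent arrays, each comparing the RNA of 1 sample with a universal mouse reference RNA. Col3a1 knockout fibroblasts, which lack a working gene for the type III collagen chain, had been transfected with either wild-type (WT) Col3a1 or the Tsk2 allele of Col3a1, with 3 arrays for each transfection. Skin came from 4-week-old female mice, with 4 arrays from Tsk2 mice and 4 from WT mice. Tsk2 is a mouse mutant with tight, fibrotic skin, and the series title places its mutation in the N-terminal propeptide of type III procollagen. The comparisons asked how the Tsk2 allele changed expression in transfected cells and in skin. All values below are log2 ratios of the sample to the reference, and each array held 41174 probes, which gave 19533 named genes. The number of arrays limits the precision of every comparison, and brightness over background was not among the values used here. The labels do not say that the 3 fibroblast samples of a group came from separate cultures, so p-values among them measure the spread between these samples, which may be technical.

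In the transfected fibroblasts, Col3a1 itself differed by less than the spread between samples. Its mean over 3 probes, 1 of which was at repeated values on all arrays, was -2.25 ± 0.063 (SD, n = 3) with the Tsk2 allele and -2.31 ± 0.074 (SD, n = 3) with the WT allele, and limma gave an adjusted p of 0.805. The probe lowest against the reference read -4.92 ± 0.019 and -4.91 ± 0.045 (SD, n = 3 each). No array of untransfected knockout cells was analysed here, and the place of the probes relative to the transfected sequence is not known, so these values do not measure how much of each allele was expressed.

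Of 27 measured interferon response genes, 3 fell over all genes tested in fibroblasts carrying the Tsk2 allele, Cxcl10, Rsad2 and Oasl1. As a list they were lower by camera with a preset correlation but not with an estimated one (adjusted p = 0.0663 with an estimated correlation). Cxcl10, an interferon-induced chemokine, was 5.66-fold lower, at 2.11 ± 0.090 against 4.61 ± 0.11 (SD, n = 3 each; adjusted p = 0.00934 by limma). Rsad2, the antiviral protein viperin, fell by 2.10 on the log2 scale, and Oasl1, an oligoadenylate synthetase-like protein, fell by 1.22. The other genes that fell were Acod1, which makes itaconate in activated macrophages, by 3.11, the alarmin cytokine Il33 by 2.17, the chemokine Ccl5 by 1.68 and the mitochondrial nucleotide kinase Cmpk2, with 25% of its values at repeated values, by 1.49. These 6 had adjusted p-values of 0.0484, and in all 7 the WT and Tsk2 samples did not overlap. Below the threshold in the same direction were Ifit1 at -0.86 (adjusted p = 0.0807), Ifi202b at -0.95 (0.0666), Phf11d at -0.88 (0.0666) and Phf11a at -0.84 (0.0987). So were 4 genes with 25% to 100% of their values at repeated values, which mark dim probes: Marchf11 at -1.23 (adjusted p = 0.0581), Cldn22 at -1.04 (0.0581), P2ry12 at -1.26 (0.0716) and Lce3c at -0.83 (0.0982).

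The genes past the threshold in the other direction were Dlx1, Ott and Aoc3. Dlx1, a homeobox gene, was listed at exactly 0 on all 3 Tsk2 arrays and at -3.96 ± 0.50 (SD, n = 3) with the WT allele, so no fold is given. Ott had 3 probe values at exactly 0, and with exact zeros taken as missing its difference was 0.50 (adjusted p = 0.372) in place of 2.90, against 5.53 (0.000223) with the most variable probe per gene. Aoc3, an amine oxidase of the cell surface, rose to 0.90 ± 0.13 from -0.41 ± 0.039 (SD, n = 3 each; adjusted p = 0.0484), with 33.3% of its values at repeated values, so no fold is given. Below the threshold in this direction were the collagen-binding integrin Itga11 at 1.37 (adjusted p = 0.112), the cholesterol exporter Abca1 at 0.95 (0.104) and Fhl1 at 0.92 (0.0982). With 66.7% to 83.3% of their values at repeated values, and some at exactly 0, so were Inpp4b at 2.06 (0.0850), Slc22a29 at 1.45 (0.0794) and Slc25a48 at 1.31 (0.0982). Inpp4b was past the threshold with array weights, and at 3.23 with the most variable probe per gene or without probes at repeated values (lowest adjusted p = 0.000430). Of 19533 genes tested, 10 passed the threshold, 3 higher and 7 lower, and 2186 had an unadjusted p under 0.05. Samples of the 2 transfections did not overlap for 20.0% of genes, where chance gives 10% on average over splits. Genes that vary together can put 1 split far from that average, and the share in other splits was not counted. The count by limma was 0 without Tsk2 replicate 1, WT replicate 3A or WT replicate 3B (1461 to 1966 genes at an unadjusted p under 0.05), 1 without Tsk2 replicate 2, and 3 without Tsk2 replicate 3 or WT replicate 1. It was 0 with WT replicates 3A and 3B taken as 1 sample (1478 genes), since the labels do not say whether these were separate transfections. It was also 0 with a replicate block for the transfection numbers (1812 genes). It was 3 with quantile normalization or each probe on its own, 5 with the most variable probe per gene, 16 with array weights and 102 when probes at repeated values were left out. The last setting kept probes at repeated values in 1 transfection only, Dlx1 among them, and how many of the 102 these were was not counted. With exact zeros as missing, 1 gene, Cxcl10, was past the threshold.

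**Figure D1:**
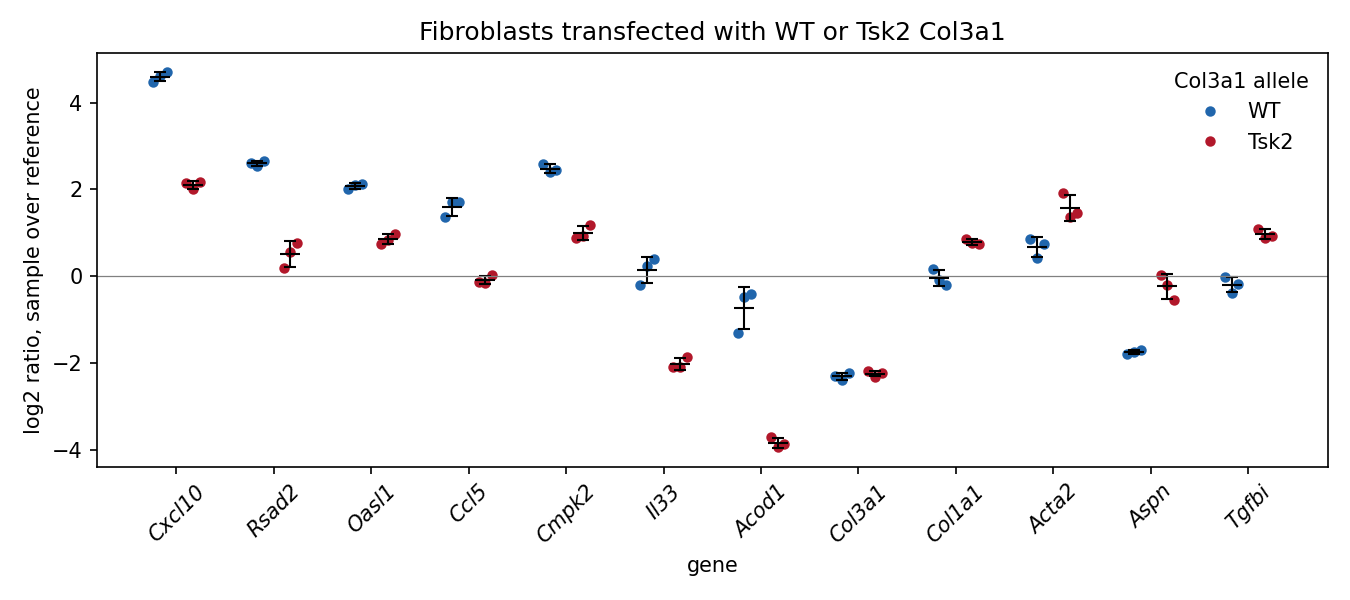
Log2 ratio of sample to reference (y axis) for 12 genes (x axis) in fibroblasts transfected with WT (blue) or Tsk2 (red) Col3a1. Points are samples, bars are the mean and SD of n = 3, and Cxcl10 lies near 4.61 with the WT allele and near 2.11 with the Tsk2 allele while Col3a1 lies near -2.3 in both.

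Among the 36 gene lists fixed before the data were examined, the interferon response list fell as a group in these fibroblasts. Of its 27 measured members, 26 were lower with the Tsk2 allele, with a mean difference of -0.59. The list mean lay above the reference with both alleles, at 1.86 ± 0.036 with Tsk2 and 2.45 ± 0.013 with WT (SD, n = 3 each). In skin it was -0.57 in both genotypes. Over all genes tested 3 members fell, and adjusted over the list alone 15 fell. The adjusted p by camera was 2.0e-16 with a preset correlation and 0.0663 with an estimated correlation. Chemokines and cytokines were not past the threshold as a list (adjusted p = 0.956), with Ccl5 and Il33 as the 2 members past it over all genes.

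Myofibroblast contractile genes, fibrillar collagens and TGF-beta target genes lay higher with the Tsk2 allele as lists. Myofibroblast contractile genes had a mean difference of 0.38 over 17 members, of which 0 passed over all genes and 10 rose when adjusted over the list alone (adjusted p = 9.84e-08, and 0.322 with an estimated correlation). Smooth muscle actin, Acta2, differed by 0.91 ± 0.20 (SE; adjusted p = 0.267), the myosin light chain Myl9 by 0.87 ± 0.13 (SE; 0.174) and calponin, Cnn1, by 0.54 ± 0.11 (SE; 0.249). Fibrillar collagens had a mean difference of 0.31 over 9 members, with 0 past the threshold over all genes and 3 that rose when adjusted over the list alone (adjusted p = 0.0114, and 0.327 with an estimated correlation). The chains of type I collagen differed by 0.83 ± 0.12 for Col1a1 and 0.77 ± 0.22 for Col1a2 (SE; adjusted p = 0.175 and 0.348), and Col5a2 by 0.53 ± 0.15 (SE; 0.350). TGF-beta target genes, at a mean of 0.17 over 20 members, were called at an adjusted p of 0.0222 (0.322 with an estimated correlation), with 0 past over all genes and 3 higher adjusted over the list alone. Its members with the lowest p were Tgfbi, a matrix protein, at 1.16 ± 0.13, Snai1 at 0.72 ± 0.14 and Ccn2, the connective tissue growth factor, at 0.43 ± 0.092 (SE; adjusted p = 0.0987, 0.230 and 0.261). Tgfb1 differed by -0.077 ± 0.098, Thbs1 by 0.13 ± 0.092 and Eln by 0.068 ± 0.28 (SE), none past the threshold.

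The other lists called in fibroblasts were sterol synthesis and dermal fibroblast genes, both higher, and cell cycle genes, lower. Sterol synthesis had a mean difference of 0.22 with 15 of 16 members higher (adjusted p = 5.88e-05, and 0.155 with an estimated correlation), and 0 of its members passed over all genes or over the list alone. Dermal fibroblast genes had a mean of 0.16 over 19 members, 2 of them higher adjusted over the list alone (adjusted p = 0.0412, and 0.322 with an estimated correlation), led by dermatopontin, Dpt, at 0.62 ± 0.10 (SE; adjusted p = 0.206). Cell cycle genes had a mean of -0.11, with 19 of 27 members lower and 0 past either adjustment (adjusted p = 0.0187, and 0.58 with an estimated correlation). The cell cycle call ended without Tsk2 replicate 3 (adjusted p = 0.107) or WT replicate 3A (0.103), that of TGF-beta targets without WT replicate 1 (0.0903), and that of dermal fibroblast genes without any sample but WT replicate 3A (0.0529 to 0.129). After quantile normalization these 3 lists had means of -0.085, 0.067 and 0.086 (adjusted p = 0.142, 0.583 and 0.328), and the cell cycle mean was -0.032 with the most variable probe per gene (0.126) and -0.17 without probes at repeated values. The cell cycle call also ended by fry (0.210) and with WT replicates 3A and 3B as 1 sample (0.0726), and that of TGF-beta targets on ranks (0.110). The dermal fibroblast call ended on ranks, with the most variable probe, with 3A and 3B as 1 sample and with exact zeros as missing (0.0517 to 0.139). Matrix lists not called by camera included proteoglycans and matricellular proteins (mean 0.21, adjusted p = 0.0557), collagen processing (0.12, 0.0744), elastic fibre genes (0.14, 0.129) and other collagens (0.17, 0.221). Proteoglycans were called higher by fry (adjusted p = 0.0166), with exact zeros as missing (0.0103) and without Tsk2 replicate 1 or WT replicate 1 (0.0490 and 0.0404). Collagen processing was called without the same samples (0.00235 and 0.0356) and elastic fibre genes without Tsk2 replicate 1 (0.0211). Both were called also without probes at repeated values (0.0449 for both). Macrophage genes were called lower by fry (0.0321), BMP targets higher without Tsk2 replicate 3 (0.0355) or probes at repeated values (0.0470) and Wnt pathway genes higher without WT replicate 1 (0.0404). Asporin, Aspn, a small proteoglycan, differed by 1.52 ± 0.16 (SE; adjusted p = 0.0982). Among matrix proteases, Mmp13, a collagenase, differed by -1.59 ± 0.21 and Adamts5 by 1.51 ± 0.23 (SE; adjusted p = 0.136 and 0.178), and that list was not called (0.987). For the uncalled lists of the unfolded protein response, sebaceous gland, neutrophils, p53 targets, endothelial cells, cytokines, B cells, glycolysis, hair, oxidative phosphorylation and skeletal muscle, mean and median had opposite signs and lay within 0.05 of 0. For adipocytes the test had the opposite sign to both.

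In skin, 11 of 24 genes of the hair follicle and hair shaft fell over all genes tested in Tsk2 mice at 4 weeks of age, and the list was called lower (adjusted p = 3.71e-16 by camera, and 0.300 with an estimated correlation). Krt33a, a keratin of the hair shaft, fell by 5.89 on the log2 scale, at 3.18 ± 1.30 against 9.07 ± 1.59 (SD, n = 4 each; adjusted p = 0.0243 by limma), and its difference was -6.54 without Tsk2 replicate 1 and -6.66 without WT replicate 4. Krt26, a keratin of the inner root sheath, fell by 6.46 and the hair shaft keratin Krt34 by 5.35, and 37.5% of the skin values of each were repeated values, so the size of these falls is uncertain. Krt26 was -7.15 without Tsk2 replicate 1 and -7.09 without WT replicate 4. Padi3, which modifies hair follicle proteins, fell by 6.13, and its difference was -7.21 without Tsk2 replicate 1, -5.50 without Tsk2 replicate 2 (adjusted p = 0.102) and -5.36 without Tsk2 replicate 4 (0.105). Keratin-associated proteins of the hair shaft made up 6 of the 12 largest falls, from -5.36 for Krtap5-1 to -6.25 for Krtap4-2, but 37.5% to 50% of the values of Krtap4-2, Krtap4-13, Krtap9-3 and Krtap21-1 were repeated values, so their sizes are uncertain too. Without WT replicate 4 the 6 ran from -6.25 for Krtap5-1 to -7.62 for Krtap4-2, and Krtap4-2 was -5.53 and Krtap4-13 -5.32 without WT replicate 2. Probes of this family were not separated from their close paralogs. Prr9 and S100a7a were also among the 12 largest falls, at -6.08 and -5.54, or -6.74 and -6.36 without WT replicate 4. Prr9 was -6.91 without Tsk2 replicate 1. All 24 measured members of the hair list were lower in Tsk2 skin, with a mean difference of -3.16. Adjusted over the list alone 19 fell.

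The mice differed within each genotype in these genes. The hair list mean was 5.16, 4.73, 5.15 and 3.72 in WT replicates 1 to 4 and 3.07, 0.55, 2.01 and 0.47 in Tsk2 replicates 1 to 4. The inner root sheath keratin Krt25 read 6.39 and 5.71 in Tsk2 replicates 1 and 3, close to the 6.05 to 7.24 of the WT mice, and 0.33 and 0.10 in Tsk2 replicates 2 and 4. The proliferation gene Mki67 was -2.26 and -2.54 in Tsk2 replicates 2 and 4 and lay between -1.01 and -0.18 in the other mice. The melanocyte and BMP target lists were also lower in Tsk2 skin, and whether this is linked to the hair genes was not tested. Melanocyte genes had a mean difference of -1.16 with 1 of 11 past the threshold over all genes and 4 adjusted over the list alone (adjusted p = 0.000767, and 0.346 with an estimated correlation), and Slc24a5, a pigment-cell ion exchanger, fell by 2.52. By fry the melanocyte call ended (adjusted p = 0.0859). BMP targets had a mean of -1.17, with 1 of 12 past over all genes and 6 over the list alone (adjusted p = 0.000103, and 0.311 with an estimated correlation), and 2 of its genes, Msx2 and Dlx3, also belong to the hair list. Smad6, an inhibitor of BMP signalling, fell by 1.79.

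**Figure D2:**
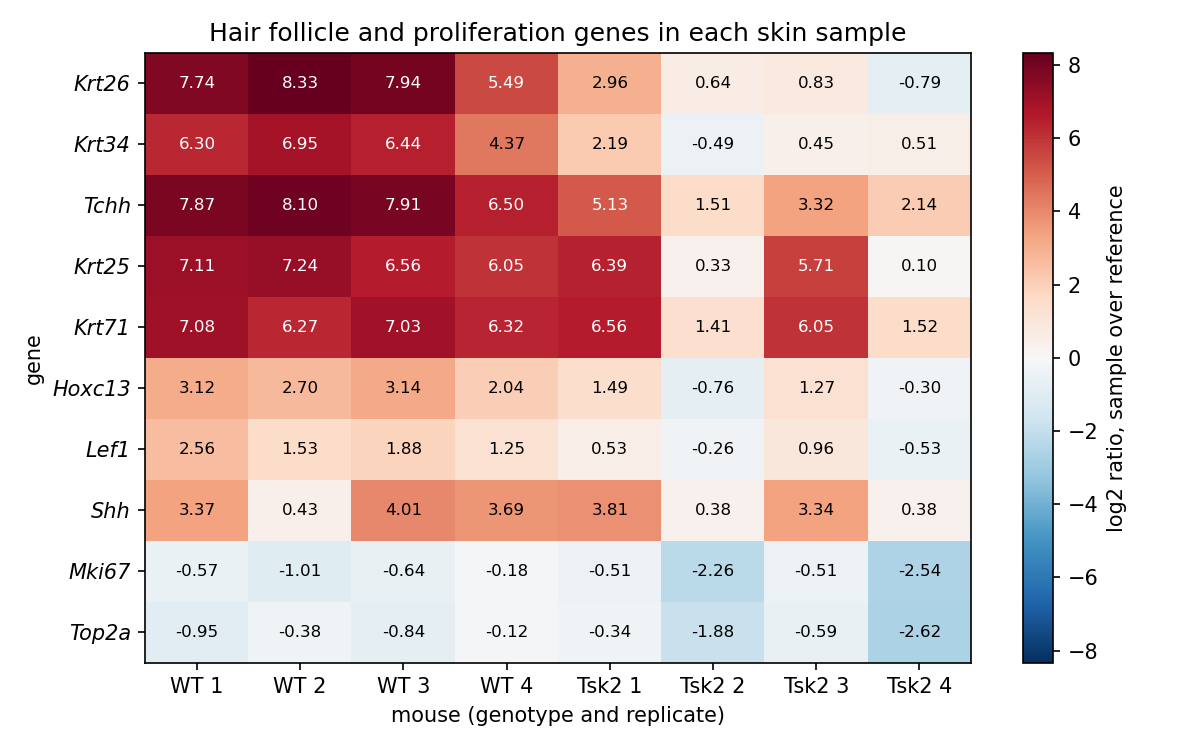
Log2 ratio of sample to reference (colour and printed value) of hair follicle and proliferation genes (rows) in each skin sample (columns, genotype and replicate). Krt26 lies between 5.49 and 8.33 in the 4 WT mice and between -0.79 and 2.96 in the 4 Tsk2 mice, while Krt25 is near the WT level in Tsk2 replicates 1 and 3.

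Extracellular matrix genes were higher in Tsk2 skin. Proteoglycans and matricellular proteins had a mean difference of 0.73, with 4 of 23 members that rose over all genes and 10 adjusted over the list alone, against 1 lower over the list alone (adjusted p = 4.81e-05, and 0.300 with an estimated correlation). Aspn was 4.33-fold higher at 4.11 ± 0.71 against 1.99 ± 0.50, and fibromodulin, Fmod, which binds collagen fibrils, was 3.60-fold higher at 1.57 ± 0.19 against -0.27 ± 0.50 (SD, n = 4 each; adjusted p = 0.0323 and 0.0229). Elastic fibre genes had a mean of 0.55, with 2 of 15 past over all genes and 7 over the list alone (adjusted p = 0.000533, and 0.233 with an estimated correlation), and Fbln1 rose by 1.15 and Ltbp2 by 1.42. Fibrillar collagens had a mean of 0.60, with 1 of 9 past over all genes, Col5a1 at 1.23 ± 0.26 (SE; adjusted p = 0.0489), and 4 over the list alone (adjusted p = 0.00892, and 0.384 with an estimated correlation). Col3a1 differed by 0.78 ± 0.26, Col1a1 by 0.95 ± 0.22, Col1a2 by 1.04 ± 0.41 and Eln by 1.01 ± 0.24 (SE), with adjusted p-values of 0.122, 0.0590, 0.177 and 0.0570. The 2 Col3a1 probes without repeated values each differed by 1.03 (adjusted p = 0.127 for both, each probe on its own). Other dermal collagens (mean 0.45; adjusted p = 0.0281, and 0.346 with an estimated correlation) had 2 of 13 members past over all genes, Col7a1 of the anchoring fibrils at 1.36 and Col6a2 at 1.20, and 6 over the list alone. Collagen processing genes (mean 0.50; adjusted p = 0.000142, and 0.346 with an estimated correlation) had 1 of 25 past over all genes, the crosslinking enzyme Lox at 1.62, and 2 over the list alone. Matrix proteases and inhibitors (mean 0.35; adjusted p = 0.0390, and 0.346 with an estimated correlation) had 1 of 24 past over all genes, Mmp16 at 0.94 (62.5% of its values repeated values), with 5 higher and 2 lower over the list alone. Dermal fibroblast markers (mean 0.53; adjusted p = 0.00346, and 0.317 with an estimated correlation) had 2 of 19, Pdgfrb at 1.24 and Lum at 1.35, with 9 higher and 2 lower over the list alone. The fibrillar collagen mean was 1.59 in WT replicate 4, the WT mouse with the lowest hair list mean, against 0.46 to 1.03 in the other WT mice and 1.48 to 1.61 in Tsk2 mice. The call of the other dermal collagens ended without Tsk2 replicate 1 (adjusted p = 0.104), on ranks (0.0513) and with exact zeros as missing (0.0968). The protease call ended without Tsk2 replicate 2 or 4 or WT replicate 1 or 3 (0.0612 to 0.0697), after quantile normalization (0.0939), with the most variable probe per gene (0.0577) and without probes at repeated values (0.179). By fry the calls of fibrillar collagens (adjusted p = 0.0728) and collagen processing (0.0565) ended, and that of fibrillar collagens also with the most variable probe per gene (0.0774).

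TGF-beta signalling genes were not called as a group in skin. The ligand and receptor list had an adjusted p of 0.522 with Tgfb3 at 1.02 and Smad6 at -1.79 past the threshold, and TGF-beta target genes had an adjusted p of 0.318 with 2 of 20 members past the threshold higher and 3 lower, among them Ctps at -2.55 and Bambi at -1.75, or -2.71 without probes at repeated values, which made up 43.8% of its values. Myofibroblast contractile genes were not called (mean 0.21, adjusted p = 0.297), though 2 of 17, Des at 1.79 and Tpm2 at 1.34, rose over all genes. Adjusted over the list alone 5 were higher and 1 lower, and Acta2 differed by 0.67 ± 0.19 (SE; adjusted p = 0.0828). Under 18 alternatives the Acta2 difference ran from 0.55 to 1.29 and passed the threshold in 3 (adjusted p by limma from 0.0230 to 0.205). Tgfb1 differed by 0.21 ± 0.15, Ccn2 by 0.76 ± 0.50 and Thbs1 by -0.30 ± 0.35 (SE), none past the threshold.

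Skeletal muscle, oxidative phosphorylation and glycolysis lists were called higher in Tsk2 skin. All 22 skeletal muscle genes were higher, with a mean difference of 0.89, 2 past over all genes and 11 over the list alone (adjusted p = 2.69e-07, 0.0569 by fry, and 0.346 with an estimated correlation). Muscle enolase, Eno3, rose by 2.27 and the fast-fibre actinin Actn3 by 2.01. Pdk4, a kinase that restrains pyruvate oxidation, was 10.9-fold higher, at 4.61 ± 1.08 against 1.17 ± 0.45, and Cox6a2, a muscle form of a cytochrome oxidase subunit, was 4.95-fold higher, at 3.71 ± 0.38 against 1.40 ± 0.23 (SD, n = 4 each; adjusted p = 0.0243 and 0.0228). Fabp3 rose by 2.52, Ankrd23 by 2.22, Adssl1 by 2.21 and Cacng1 by 2.24. Also among the 12 largest rises were Pyy at 2.42, Asb5 at 2.27, Adra2c at 2.25 and Bcl2l15 at 2.16 (adjusted p = 0.0330, 0.0290, 0.0360 and 0.0290 by limma). Pyy and Adra2c each had 1 probe value at exactly 0. The largest rise in skin, 4.30 for Tceal7, rests on a WT mean that includes 2 values at exactly 0. Oxidative phosphorylation genes had a mean of 0.38 with 21 of 22 higher, 0 past over all genes and 11 over the list alone (adjusted p = 3.49e-05, and 0.346 with an estimated correlation). Hypoxia and glycolysis genes had a mean of 0.39, with 8 members higher over the list alone against 1 lower, Ero1a at -1.62, which was also the only member past over all genes (adjusted p = 0.00284, and 0.397 with an estimated correlation). That call ended without WT replicate 4 (adjusted p = 0.0630), by fry (0.0728) and after quantile normalization (mean 0.22, adjusted p = 0.151).

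Markers of other skin cell types also differed. Mast cell genes had a mean difference of 0.64, with 2 of 12 past over all genes, Gata2 at 1.25 and the histamine-forming enzyme Hdc at 1.13, and 7 over the list alone (adjusted p = 0.000533, and 0.233 with an estimated correlation). Adipocyte genes were higher in all 17 members with a mean of 0.55 (adjusted p = 0.00111, and 0.346 with an estimated correlation), with 1 past over all genes and over the list alone, the glucose transporter Slc2a4 at 1.45. Sebaceous gland genes had a mean of 0.59, with 3 of 13 past over all genes, among them Acsbg1 at 1.20 and Scd3 at 1.11, and 6 over the list alone (adjusted p = 0.00284, and 0.346 with an estimated correlation). The adipocyte and sebaceous lists as fixed share Pparg and Cidea. Endothelial (mean 0.42; adjusted p = 0.0281, and 0.346 with an estimated correlation) and Schwann cell genes (mean 0.32; adjusted p = 0.0456, and 0.311 with an estimated correlation) were called higher too, and Cnp, a myelin enzyme, rose by 1.29 as the 1 of 11 Schwann cell genes past over all genes, while 0 of 16 endothelial genes passed. The endothelial call ended without Tsk2 replicate 2 (adjusted p = 0.0924) or WT replicate 4 (0.0707) and with exact zeros as missing (mean 0.23, adjusted p = 0.0749), with the most variable probe per gene (0.0906) and by fry (0.0728). The Schwann cell call ended without Tsk2 replicate 1, 2 or 4 or WT replicate 1 or 4 (0.0516 to 0.111), with the most variable probe per gene (0.0593), with exact zeros as missing (0.109) and without probes at repeated values (0.0681). Keratinocyte lists were not called, with medians of 0.19 for suprabasal and 0.32 for basal genes (adjusted p = 0.973 and 0.267).

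The remaining lists called in skin were lower in Tsk2 mice. Cell cycle genes were lower in all 27 members with a mean of -0.51 and 0 past the threshold (adjusted p = 0.000533, 0.336 by fry, and 0.572 with an estimated correlation). The list mean was -2.07 and -2.28 in Tsk2 replicates 2 and 4, but -0.85 and -0.77 in Tsk2 replicates 1 and 3, above the -1.08, -1.06 and -1.11 of WT replicates 1 to 3. The difference was -0.32 without Tsk2 replicate 2 and -0.25 without Tsk2 replicate 4. Unfolded protein response genes had a mean of -0.30, with 7 of 25 lower over the list alone (adjusted p = 0.00284, and 0.300 with an estimated correlation), and the chaperone Hspa5 differed by -0.75 ± 0.18 (SE; adjusted p = 0.0569). Sterol synthesis genes had a mean of -0.34 (adjusted p = 0.00470, 0.175 by fry, and 0.449 with an estimated correlation). Their list mean was -0.0098 and -0.074 in Tsk2 replicates 3 and 4, but 0.49 and 0.56 in Tsk2 replicates 1 and 2, within the 0.48 to 0.66 of WT mice. Wnt pathway genes had a mean of -0.35 with 5 lower and 1 higher over the list alone (adjusted p = 0.0289, and 0.346 with an estimated correlation). Its member Lef1, at -1.63 (adjusted p = 0.0604 by limma), also belongs to the hair list. The Wnt call ended without Tsk2 replicate 4 (0.0653) or WT replicate 4 (0.112), by fry (0.0645), with the most variable probe per gene (0.0608) and without probes at repeated values (0.0514). Interferon response genes had a mean of 0.0024 in skin with 0 of 27 past either adjustment (adjusted p = 0.977), and T cells, macrophages, B cells, neutrophils, blood, p53 targets, immediate early genes and cytokines were not called by camera. T cell genes, at a mean of 0.19 with 11 of 13 higher and 3 past over the list alone, were called higher by fry (adjusted p = 0.0131, and 0.101 by camera). Macrophage genes were called higher without WT replicate 2 or WT replicate 4 (0.0269 and 0.00462). List means of the genotypes overlapped also for collagen processing, melanocyte, glycolysis and Wnt pathway genes. Mean and median differed in sign for suprabasal keratinocytes (-0.028 and 0.19), blood (-0.31 and 0.33), neutrophils (-0.15 and 0.073), cytokines (-0.066 and 0.099) and p53 targets (-0.0100 and 0.015), none of them called, and the test had the sign of the median for suprabasal keratinocytes, blood and cytokines.

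Of 19533 genes tested in skin, 568 passed the threshold, 373 higher and 195 lower, and 567 of them did not overlap between genotypes. Samples did not overlap for 16.1% of all genes, where chance gives 2.86% on average over splits, and the share in other splits was not counted. The count by limma was 0 without Tsk2 replicate 2, 3 or 4 or WT replicate 1, 2 or 3, with 3473 to 4145 genes still at an unadjusted p under 0.05, and it was 1827 without WT replicate 4. It was 1726 with array weights, 2814 in 1 fit of all 14 arrays and 2200 without probes at repeated values in both genotypes.

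**Figure D3:**
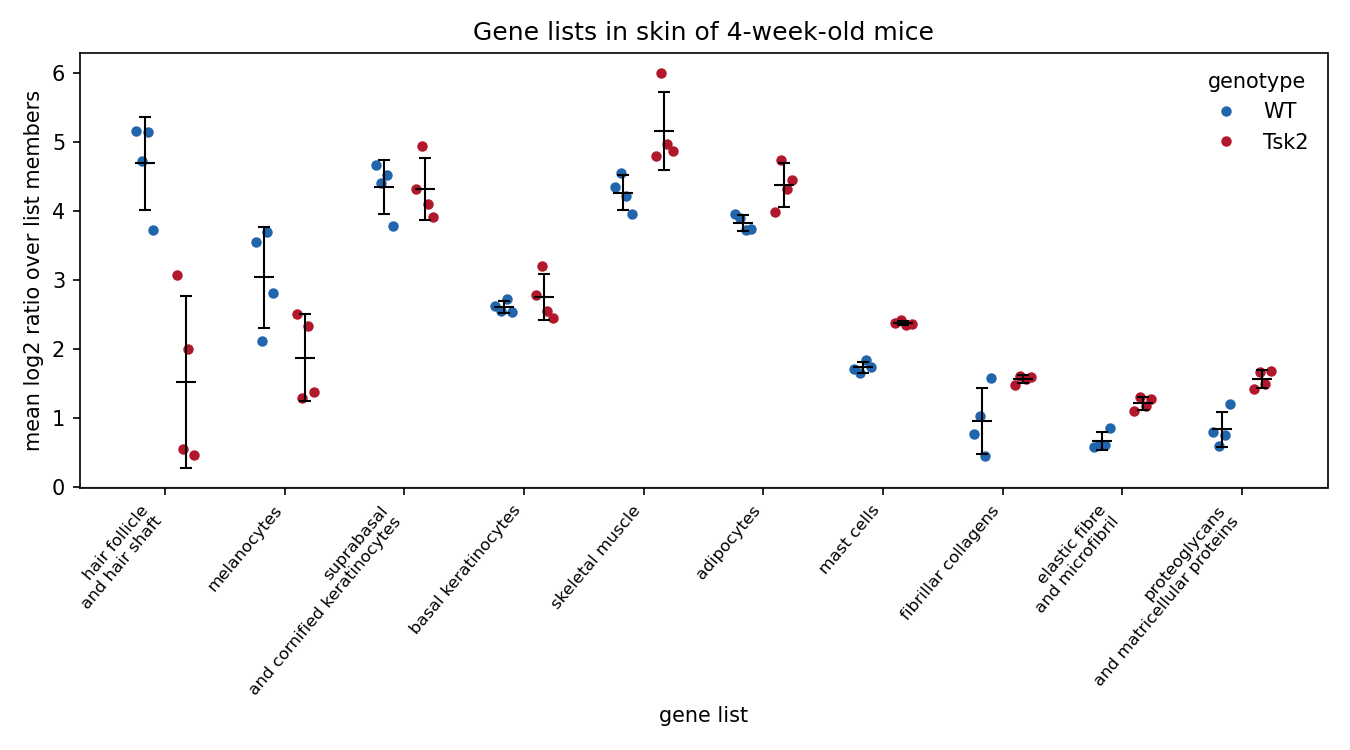
Mean log2 ratio over the members of 10 gene lists (y axis) in skin of WT (blue) and Tsk2 (red) mice, with points for mice and bars for the mean and SD of n = 4. The hair list lies at 3.72 to 5.16 in WT mice and at 0.47 to 3.07 in Tsk2 mice, while the suprabasal keratinocyte list overlaps between genotypes.

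The difference of the Tsk2 effect between skin and transfected fibroblasts passed the threshold for 273 genes in 1 fit of all 14 arrays. Of these, 176 had a more positive effect in skin and 97 a more negative one. That fit shares 1 spread per gene between cultured cells and skin, which need not be alike. In such a fit the skin comparison gave 2814 genes in place of 568, and the fibroblast comparison 7 in place of 10. Its p-values may therefore be too small for genes that vary more in skin. Il33 showed the lowest p, with a difference of 3.28 ± 0.35 (SE; adjusted p = 0.0110 by limma), and Acod1 differed by 3.13 ± 0.43 (SE; 0.0148), both lower in Tsk2 fibroblasts. In skin Il33 differed by 1.11 ± 0.26 in the other direction (SE; adjusted p = 0.0601), which is part of its difference. The 12 largest negative differences ran from -4.89 for Ctse to -6.32 for Krt26, and apart from Ctse, S100a7a, Prr9 and Dlx1 they belonged to hair keratins and keratin-associated proteins. For Krt26, Krtap4-13, Krt34 and Krtap22-2, 64.3% of the values were repeated values, for Krt33a and Prr9 42.9%, and Dlx1 was listed at exactly 0 on the Tsk2 fibroblast arrays, so the sizes and their order are uncertain. Without WT replicate 4 those other than Dlx1 and Krt34 ran from -5.67 for Ctse to -7.25 for Krtap4-13. As lists, interferon response genes differed by 0.59 and hair genes by -3.21 (adjusted p = 0.00157 and 1.35e-15, and 0.427 and 0.234 with an estimated correlation). The fibrillar collagen list, with means of 0.31 in fibroblasts and 0.60 in skin, was not shown to differ between them (difference 0.29, adjusted p = 0.188), nor was Col1a1 (0.12 ± 0.29, SE; adjusted p = 0.877). The count of 273 became 7 with WT fibroblast replicates 3A and 3B as 1 sample, 6 to 61 without any 1 fibroblast sample, 42 to 543 without any 1 mouse other than WT replicate 4, and 1492 without that mouse. It was 130 with each probe on its own, 838 without probes at repeated values in every group and 1478 with array weights.

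Across genes, the measured effects in the 2 systems showed little correlation, with Pearson r = 0.0383 and Spearman rho = 0.0594 over 19533 genes, which are not independent replicates. Noise in either effect lowers such a correlation and was not allowed for, so the value does not show that the effects are unrelated. No gene was past the threshold in both systems by limma. At an unadjusted p under 0.05, 245 genes were higher in both, where 142 would be shared by independent lists, and 136 were lower in both, where 110 would be. In opposite directions, 160 were higher in skin and lower in fibroblasts, where 145 would be, and 107 were lower in skin and higher in fibroblasts, where 108 would be. Ordered by the larger of their 2 p-values, the first of those higher in both were Fhl1, Aspn, Tgfb3, Cstad, Tgfbi, Ptx3, Myorg, Dner, Nacad and Col1a1. These overlaps were not set against other splits of the samples.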

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

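The tests weighed below for hair, matrix and interferon genes were chosen after those results were seen, as were the test of gene lists for the difference between systems and its splits with WT replicates 3A and 3B as 1 sample, and the other splits of the samples were planned before. Regrouping the 8 skin arrays in 35 ways gave 568 genes in the real split and at most 0 in the others. So 1 of 35 splits was as large, the smallest share these splits can give, which makes chance unlikely there but does not exclude it. For skin lists the real split called 22 and the highest other split 20, again 1 of 35, with a median of 7 in the others, so list calls at the preset correlation also arose in splits that mix the genotypes. The 10 splits of the 6 fibroblast arrays are too few for a share under 0.05. The real split gave 10 genes and 7 lists, and the highest of the others gave 0 genes and 5 lists, with 1 split as large in each case. For the difference between systems, 1 of 100 drawn splits reached 273 genes, the real one, and the highest other gave 139. With WT replicates 3A and 3B as 1 sample the count was 7, again reached by 1 of 100 splits, the real one, with a highest other of 1. For both counts the splits make chance unlikely only as a grouping with no effect in either system, since both systems were regrouped. A skin effect alone would also make the real split the largest, so these splits do not show that the effects differ. The correlation of the effects, 0.0383, was reached in size by 9 of 100 drawn splits with a highest of 0.0641, so chance cannot be excluded for it.

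Hair genes were lower in Tsk2 skin. A smaller share of epidermis would lower the other epidermal genes by about as much, and their median difference was 0.30 over 36 basal and suprabasal genes, with quartiles of -0.34 and 0.42, against -2.88 for the hair list, which argues against it. Hair-cycle stage stays open. The hair list mean ranged over 2.60 among the 4 Tsk2 mice, from 0.47 to 3.07, and neither stage nor exact birth date is in the labels, so a shift of stage between litters and an effect of the allele on the follicle cannot be told apart.

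Matrix genes were higher in Tsk2 skin, at a mean over the 85 genes of the 5 matrix lists of 0.98 ± 0.065 in Tsk2 and 0.41 ± 0.26 in WT mice (SD, n = 4 each), a difference of 0.57 (exact permutation p = 0.0286, two-sided, the smallest 4 against 4 can give). More muscle in the Tsk2 samples as the whole cause is argued against, since within genotypes the slope of the matrix mean on the muscle mean was -0.11 where the difference between genotypes needs 0.64 (exact permutation p = 0.00694 against that slope, 576 arrangements within genotypes), and without each mouse in turn p was at most 0.0278, with slopes from -0.71 without Tsk2 replicate 2 to 0.035 without WT replicate 4. A link to hair-cycle stage cannot be told apart from genotype, since the slope within genotypes on the hair list mean was -0.12, against -0.18 between genotypes (exact permutation p = 0.488). That rests on WT replicate 4, without which the slopes were -0.050 and -0.20 (exact permutation p = 0.0486), and the mice per genotype are few. The tests on muscle and hair both take the slope between genotypes as fixed, though it came from the same mice, so their p-values may be too small. A direct effect of the allele stays among the open explanations.

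Interferon genes were lower with the Tsk2 allele in fibroblasts. Values set at 0 or repeated are argued against. The list mean of -0.59 was -0.57 with exact zeros taken as missing and -0.59 with probes at repeated values in both groups left out. It was -0.60 over the 22 of 27 members without such a value on any of the 6 arrays. The list stayed past the threshold each time by camera at the preset correlation (adjusted p = 0.0663 with an estimated correlation over all values). A single deviating sample is argued against too, since the highest adjusted p of the list without each sample in turn was 3.69e-12 at the preset correlation, with means from -0.61 to -0.57. A difference between the transfections other than the allele, in plasmid preparation or uptake, may also lower such genes and cannot be told apart from the allele. The Col3a1 probe that differed most between transfections did so by 0.34, and it is not known whether it reads the transfected sequence.

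Values far from the other 3 mice of a group were found in 21 of 232 sets of 4. Chance gives about 1 in 20, or 11.6, on average. The sets are not independent, since genes vary together and lists hold some of these genes, so 21 cannot be weighed against 11.6. Of the 21 values, 15 belong to WT replicate 4. In WT replicate 4 these were Eno3 at 2.60, Padi3 at 4.01, Krtap9-3 at 2.96, Krtap21-1 at 1.53, Krtap6-1 at 2.45, Krtap5-1 at 2.59, Col5a2 at 1.21, Col7a1 at 3.25, Lox at -2.01, Mmp2 at 0.78, Ero1a at -2.60 and Ldha at -1.17. Its list means stood apart for elastic fibre genes at 0.86, BMP targets at 1.48 and cell cycle genes at -0.68. Over all probes, WT replicate 4 correlated with the 4 Tsk2 mice at Pearson r from 0.785 to 0.872, highest with Tsk2 replicate 1. With WT replicates 1, 2 and 3 its r was 0.812, 0.743 and 0.775. So it was no closer to the other WT mice than to the Tsk2 mice, which bears on every skin comparison that holds it as WT. The cause was not tested. In WT replicate 3 Cenpe was -1.27 and the TGF-beta ligand and receptor list 0.14. In Tsk2 replicate 1 Krt33a was 5.13 and Krtap5-1 0.69, and in Tsk2 replicate 2 P3h3 was 0.042 and the skeletal muscle list 6.0.

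The effect of Tsk2 in skin minus that in fibroblasts was past the threshold for 273 of 19533 genes and for 44 of 137 named genes, some of which were named because they passed it. Genes that fell in fibroblasts differed by 3.13 for Acod1, 2.10 for Ccl5 and 3.28 for Il33, of which 1.11 lay in skin, where it was not past the threshold. Muscle and metabolic genes differed by 3.59 for Pdk4, 2.39 for Fabp3, 2.24 for Cox6a2, 2.57 for Asb5, 2.22 for Eno3, 1.99 for Ankrd23, 2.63 for Adssl1, 2.25 for Actn3, 2.58 for Mrln, 2.54 for Kcne1l and 2.46 for Pacsin3. Further positive differences were 2.41 for Bcl2l15, 1.59 for Fmod, 2.0 for Acsbg1, 1.87 for Hdc, 1.74 for Lum, 2.83 for Cytl1, with 50% of its values repeated values, 2.73 for Clec2d, 2.67 for Fam180a and 2.43 for Ptpn22. Hair keratins and keratin-associated proteins gave -6.32 for Krt26, -6.26 for Krtap4-13, -5.49 for Krt33a, -6.07 for Krtap6-1, -5.41 for Krtap5-1, -5.09 for Krt34, -3.16 for Krtap8-1, -5.25 for Krtap5-4 and -5.00 for Krtap22-2, and 64.3% of the values of Krt26, Krtap4-13, Krt34 and Krtap22-2, and 42.9% of those of Krt33a, were repeated values, so these sizes are uncertain. The remaining negative differences were -5.93 for Prr9, with 42.9% of its values repeated values, -5.12 for S100a7a, -4.89 for Ctse, -5.36 for Dlx1, listed at 0 on the Tsk2 fibroblast arrays, -2.20 for Slc22a29, -1.24 for Slc25a48, -1.58 for Itga11, -1.64 for Timp3, -2.21 for Smad6, -1.51 for Ero1a, -2.77 for Ctps and -2.18 for Bambi.

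Gene lists differed between the systems in 18 of 36 cases by camera with a preset correlation and in 0 with an estimated one. Mean differences were -3.21 for hair genes, 0.88 for skeletal muscle, 0.39 for oxidative phosphorylation, -0.57 for sterol synthesis, -1.27 for BMP targets, 0.59 for interferon response and 0.69 for mast cells. They were -0.30 for the unfolded protein response, -1.11 for melanocytes, -0.49 for the Wnt pathway, 0.38 for hypoxia and glycolysis, 0.38 for collagen processing, 0.56 for adipocytes and 0.59 for sebaceous gland. The others were 0.41 for elastic fibre genes, 0.51 for proteoglycans, -0.40 for the cell cycle and -0.32 for TGF-beta targets.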

How the results depend on the processing

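The alternatives on exact zeros and repeated values were chosen after seeing the data. The one on repeated values kept probes that had them in only some of the groups compared. No gene or list called as reported had the opposite sign under an alternative, with probes on their own not compared. Of genes called only under an alternative, 13 in skin and 1 for the difference between systems had the opposite sign to the reported difference. In fibroblasts the 10 genes became 3 with quantile normalization (2 higher and 1 lower, against 3 and 7), 3 with each probe on its own, 5 with the most variable probe per gene, 16 with array weights, 0 with WT replicates 3A and 3B as 1 sample (1478 at an unadjusted p under 0.05 by limma), 1 with exact zeros as missing and 102 without probes at repeated values, and 0 to 3 with 1 sample left out. In skin the 568 genes became 1726 with array weights, 2814 in 1 fit of all 14 arrays and 2200 without probes at repeated values, of which 543 were shared, and 0 to 1827 with 1 mouse left out. For the difference between systems, 273 genes became 130 with each probe on its own, 1478 with array weights, 7 with 3A and 3B as 1 sample, 838 without probes at repeated values and 6 to 1492 with 1 array left out. Lists called in fibroblasts fell from 7 to 0 with an estimated correlation (4 at an unadjusted p under 0.05), 4 with quantile normalization and 5 on ranks, with the most variable probe or with 3A and 3B as 1 sample, against 8 with fry, which gained proteoglycans and macrophages, and 10 without probes at repeated values, which gained collagen processing, elastic fibre genes and BMP targets. The lost ones were cell cycle (quantile normalization, fry, most variable probe, 3A and 3B as 1), TGF-beta targets (quantile normalization, ranks) and dermal fibroblasts (quantile normalization, ranks, most variable probe, 3A and 3B as 1, replicate block, exact zeros as missing). In skin they went from 22 to 0 with an estimated correlation (5 unadjusted), 14 with fry, 21 on ranks, 20 with quantile normalization, 17 with the most variable probe and 19 with exact zeros as missing or without probes at repeated values. Fry lost fibrillar collagens, collagen processing, Wnt, cell cycle, glycolysis, sterol synthesis, muscle, melanocytes and endothelium and gained T cells, ranks lost other collagens, and quantile normalization proteases and glycolysis. The most variable probe lost fibrillar collagens, proteases, Wnt, endothelium and Schwann cells, exact zeros as missing lost other collagens, endothelium and Schwann cells, and leaving out repeated values lost proteases, Wnt and Schwann cells. Among named genes in skin, the settings other than leaving out mice kept the side of the threshold 681 times, brought a gene past it 70 times and lost it 18 times, in fibroblasts 681, 32 and 47 times, and for the difference between systems 303, 1 and 24 times. With 1 array left out these were 293, 16 and 307 in skin, 328, 0 and 56 in fibroblasts and 260, 2 and 200 for the difference. The correlation of effects was 0.0208 to 0.0487 with 1 array left out. Leaving out samples lowers the degrees of freedom, and for the other changes the cause was not tested. Only the transfection numbers 1 and 3 occur in both groups, 3 for both 3A and 3B. Same-numbered samples deviated together by r of 0.019, 0.0082 and 0.017 across genes. These lay above the -0.025 to 0.0067 of samples with unlike numbers, but near 0, so the numbers were not taken to pair them. With the replicate block 0 genes passed (1812 at an unadjusted p under 0.05) and 6 of the 7 lists. Signal over background is unknown, so how far dim probes limit these counts was seen only through the repeated values.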

Other observations

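The tests of this part were written before their results were seen, but the list was chosen after Igf2 and H19 had been noticed in skin. Igf2, a fetal and juvenile growth factor, and H19, its neighbouring imprinted RNA, were higher in Tsk2 skin. Igf2 was 1.11 ± 0.15 against -0.81 ± 0.44 and H19 2.53 ± 0.13 against 0.91 ± 0.35 (SD, n = 4 each; adjusted p = 0.0229 for both by limma), with WT replicate 4 highest among WT mice at -0.20 and 1.38. Both genes decline with postnatal growth in many tissues, so a candidate explanation is that the Tsk2 mice were at an earlier stage of growth than the WT mice. If so, other genes that decline with growth should be higher as a set. Over 18 of 19 such genes, fixed before this test and without Igf2 and H19, the mean difference was 0.27. Of them 15 were higher and 3 lower, with 0 past the threshold over all genes and 6 higher adjusted over the list alone.

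That result goes with the hypothesis but is narrow. Camera gave p = 0.0166 with a preset correlation and 0.0411 with an estimated one, and among the 35 splits of the 8 mice the real one was the largest, at 0.27 against 0.26 for the next (exact permutation p = 0.0286, the smallest 4 against 4 can give). Slc38a4 differed by 0.90 ± 0.24, Meg3 by 0.84 ± 0.24, Dlk1 by 0.78 ± 0.23 and Sgce by 0.70 ± 0.20 (SE), while Mycn, also a hair follicle gene, differed by -1.60 ± 0.69 and Mest by 0.0053 ± 0.21. Ages in days and body weights are not in the labels. An effect of the allele on growth, a few days' difference in age between litters, and a higher share of mesenchymal cells, which express several of these genes, stay open and may also bear on the hair and matrix differences.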
